A study of Homo sapiens with 14 samples.

How the data were processed

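RNA of primary dermal fibroblasts was measured on 14 Affymetrix arrays. The cells carried a stably selected short hairpin RNA plasmid, either a control construct or 1 of 3 constructs against KDM4C, a histone lysine demethylase of the JmjC family. Selected clones were the unit of the design: 2 clones of the control construct, 2 of construct 1, 2 of construct 2 and 1 of construct 3, each with 2 arrays. The labels do not say whether the 2 arrays of a clone came from separate cultures. They were averaged on the log2 scale, and each clone counted as 1 replicate. P-values of the comparisons between constructs therefore measure the spread between clones. The comparison pooled over the 3 constructs has no term per construct. Its spread therefore also holds differences between constructs, and clones of the same construct count in it as independent.

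The deposited values are probe set intensity on a linear scale, made with MAS5 per the submitters' processing notes. The software version is not given in the sources used here. The mean signal after trimming 2% from each end lay between 500.07 and 500.08 on every array, so the deposited signals had already been scaled to a common target, and no further scaling was applied. Array medians lay between 59.4 and 91.8. The number of arrays and of clones limits the precision; no depth applies to this assay.

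The table held 54675 probe sets, of which 62 were control probe sets. In the platform annotation, 41091 had 1 gene symbol, 1801 had several and 11721 had none; 41037 of the first kind matched the current gene table by gene identifier, and 0 symbols changed. Probe sets of XIST and of Y-linked genes were left out, 95 in all. Each gene was represented by its probe set with the highest mean, which gave 19740 genes. Genes whose mean log2(signal + 16) was above the median of all probe sets, a signal of 61.7, were kept, and 12596 genes were tested. The offset of 16 shrinks fold changes of weakly expressed genes. Where clone means of a named gene lay under the filter signal, a lower bound was computed with those means set at it, a step added after the data were examined.

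Clone means were fitted with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, and two-sided p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The pooled comparison set 5 clones labelled shKDM4C against 2 control clones, with 5 residual degrees of freedom. A model with a term per construct, with 3 residual degrees of freedom, gave the comparison of each construct with the controls and of construct 2 with construct 1. The lone clone of construct 3 was assumed to vary like the others. Differences between 2 clones of a construct were tested on the 14 arrays with a term per clone and 7 residual degrees of freedom; those p-values rest on the spread between the 2 arrays of a clone, which may be technical alone. The 21 ways of choosing 2 of 7 clones limit the two-sided exact permutation test used here, 2 times the smaller tail, to p = 0.0952 or more. The tests were tried on simulated data with 12596 genes, 200 of them changed. The pooled comparison recovered 57.5% of changes of 2 on the log2 scale, 90.5% of changes of 4 and 98.5% of changes of 6. The comparison of construct 1 recovered 19.5%, 84% and 93.5% of them. Changes simulated for the pooled comparison had the same size in all 3 constructs, over noise set by the spread between clones of a construct. Recovery of changes that differ between constructs was not simulated.

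Of 46 gene lists written before the data were examined, 45 had at least 5 tested members and were tested with camera at a preset correlation of 0.01. An estimated correlation and the rotation test fry stand beside it. Named genes followed a rule of the same date. In the pooled comparison these were the 12 largest rises and 12 largest falls among genes past the threshold, with the 5 clone means all on the same side of both controls. Where fewer than 12 passed, the list was filled by the smallest unadjusted p. Per construct, and between clones of a construct, the 5 largest changes each way past the threshold were named, and for each list called the 4 members with the largest change. LOC symbols were skipped. Unadjusted gene counts, list shifts and simulated agreement between constructs against the shared controls were added as context.

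The sources used here give no scan batch. A possible batch was therefore sought in the arrays, after the data were examined, by 3 rules that gave 3 different groupings. The largest gap in the signal of the hybridisation spikes BioB and BioC set control clone 1 and construct 2 clone 1 apart. A correlation above 0.6 with control clone 1 over probe sets under the filter added construct 1 clone 1 to that pair; this threshold was set with the correlations in view. An average-linkage tree of the same probe sets set construct 1 clone 2 alone apart. The first 2 groupings, called the spike grouping and the low-signal grouping, leave a control clone in each batch, and both were carried through. The third has no control clone in its small batch, and leaving out that clone covers it. By order of deposit, construct 2 clone 2 and the clone of construct 3 came after the other arrays, with no control clone among them. For these clones, a difference from the controls cannot be told apart from a difference between the sets deposited first and later.

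Alternatives fixed beforehand were quantile normalization, offsets of 1 and 64, other filters, variance priors and probe set choices, fits to the 14 arrays or to those first in the order of deposit, and leaving out each clone. In the fits with the clone as a random block, lists were tested with the preranked form of camera. Each of those fits used 1 correlation for all genes and counted arrays in its degrees of freedom. Genes that vary more between clones are therefore called too readily there. Figures were drawn with matplotlib 3.10.9.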

Results

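The series asked how expression changed in primary dermal fibroblasts after stable selection for hairpin constructs against KDM4C, a demethylase of histone H3 lysines. Signals of 12596 genes were compared in 7 clones, 2 with a control construct and 5 labelled shKDM4C, over 3 non-overlapping constructs. The median spread over genes was 0.169 (SD, log2 scale) between arrays of a clone and 0.353 between clones of a construct.

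KDM4C transcript was not lower in most clones labelled shKDM4C. Its signal was 265 and 231 in control clones 1 and 2. It was 513 and 677 in the clones of construct 1, 380 and 155 in those of construct 2, and 478 in the clone of construct 3. Construct 2 clone 2 alone lay below both controls, at 0.652 of the control level. The pooled log2 difference was 0.66 ± 0.49 (SE, 5 clones against 2; limma, unadjusted p = 0.216, adjusted p = 0.663; two-sided exact permutation p = 0.381). Construct 1 stood at 1.21 ± 0.45 (limma, unadjusted p = 0.0348, adjusted p = 0.257), construct 2 at -0.01 ± 0.45 (unadjusted p = 0.98, adjusted p = 0.999) and construct 3 at 0.92 ± 0.55 (unadjusted p = 0.145, adjusted p = 0.968). The other 3 KDM4C probe sets lay between percentiles 7 and 35.5 of signal and give no usable level. Of the paralogs, KDM4B differed by 0.93 ± 0.38 (limma, unadjusted p = 0.0399, adjusted p = 0.442) and KDM4A by 0.43 ± 0.21 (unadjusted p = 0.0727, adjusted p = 0.495), while KDM4D lay under the filter. Within the batches of the spike grouping, KDM4C differed from the control clone by 0.49 and 0.78, and within those of the low-signal grouping by 0.70 and 0.67. Without each clone in turn the KDM4C difference lay between 0.48 and 0.98, the highest without construct 2 clone 2 (0.98 ± 0.28; limma, unadjusted p = 0.00948, adjusted p = 0.296), and without both clones of construct 1 it was 0.30 ± 0.48 (unadjusted p = 0.56, adjusted p = 0.956). Because the transcript went against the label in 4 of 5 clones, every direction given here is that of clones labelled shKDM4C, not of cells shown to hold less KDM4C.

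**Figure D1:**
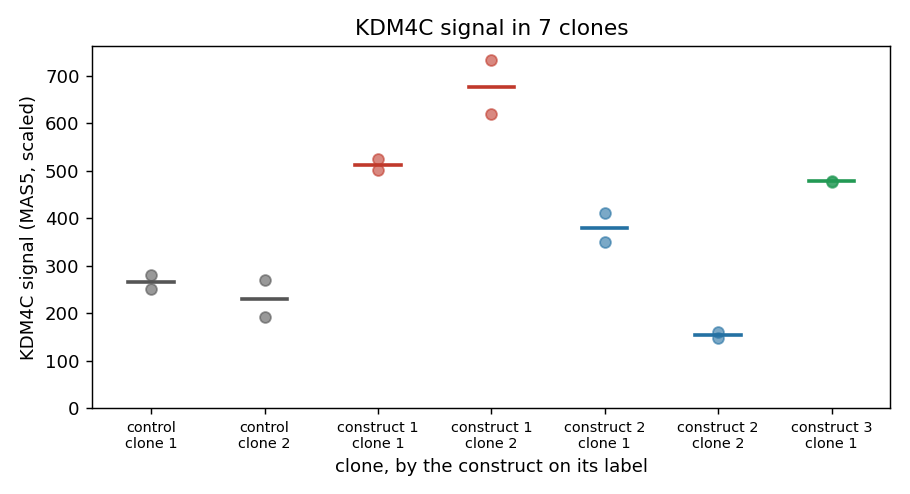
KDM4C signal (MAS5, scaled, vertical axis) in 7 clones grouped by the construct on the label (horizontal axis); each point is an array and each bar the mean of 2 arrays. Construct 2 clone 2, at 155, is the clone below both controls, which stand at 265 and 231.

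In the pooled comparison, 6 genes passed the threshold and all 6 were higher in clones labelled shKDM4C. SIM1, a transcription factor of the bHLH-PAS family, rose by 4.43 ± 0.30 on the log2 scale (SE; limma, adjusted p = 0.00416), from signals of 7.21 and 23.5 in the controls to between 469 and 747. These control signals lie under the filter signal of 61.7, and with the controls set at it the difference is at least 3.06. INHBB, the beta B subunit of inhibins and activins, rose by 3.95 ± 0.43 (limma, adjusted p = 0.0307), and EDIL3, a matrix ligand of integrins, by 3.81 ± 0.35 (adjusted p = 0.0169). TRO rose by 2.96 (at least 1.91 on that basis), LOXL4, a lysyl oxidase that crosslinks collagen, by 2.56, and CDKN2B, which encodes the cyclin-dependent kinase inhibitor p15, by 2.42. The second probe set of LOXL4 had the opposite sign. Higher genes that missed the threshold but separated all clones from both controls were HAPLN1 (5.26), GASK1B (4.78), GDF5 (3.08), ADGRL2 (2.39), TENM4 (2.02) and ADAMTS12 (2.01), with adjusted p from 0.0597 to 0.11 in limma. A control clone lay under the filter signal for HAPLN1 (at least 4.59), GDF5 (at least 2.90) and TENM4 (at least 1.86); the second probe set of ADGRL2 had the opposite sign.

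No gene passed the threshold in the downward direction in this fit. In limma 1 lower gene passed at an offset of 64, with constructs weighted equally or without construct 1 clone 2, 4 passed in the arrays deposited first, and 63 or 38 with the clone as a random block, without or with the replicate block. In the main fit the lower genes nearest to the threshold were SAMD11 (-2.36; limma, adjusted p = 0.0794) and the stromelysin MMP10 (-3.32, adjusted p = 0.0825). Among the other 10, the ID proteins, which bind and inhibit bHLH transcription factors, stood at -3.18 for ID1, -2.36 for ID3 and -2.10 for ID4. MALL stood at -3.61, TPD52 at -2.66, EVI2B at -2.52, ELFN2 at -2.28, NEMP1 at -2.03, GULP1 at -1.85 and the transcription factor TFAP2A at -1.38. Only 1 of the 3 other probe sets of ELFN2 had the same sign. For GULP1, TPD52 and ID4, 3 of 4 other probe sets each did. For MMP10 and TPD52 all 5 labelled clones lay under the filter signal, and with them set at it the differences are -2.42 and -2.05. At an unadjusted p under 0.05 there were 1339 genes, 704 higher and 635 lower. All 5 clone means lay above both controls for 1153 genes and below both for 1159. That is 18.36% of genes, against 9.52% on average over all such splits of the clones. How far this share varies between splits was not computed, so an excess over chance is not established. Setting the clones of construct 1 apart gave 1788 genes at an unadjusted p under 0.05 (limma). Setting clone 1 of construct 1 and clone 1 of construct 2 apart gave 1600. The remaining splits gave fewer than the labels' own. The count of 6 rose to 26 in the arrays deposited first and to 185 or 132 with the clone as a random block, without or with the replicate block. It fell to 3 with a filter at the upper quartile, to 2 without either control clone, without construct 1 clone 2 (1 higher and 1 lower) or with constructs weighted equally (1 higher and 1 lower), to 1 without construct 2 clone 1 or construct 3 clone 1, and to 0 in limma without both clones of construct 1, with 1012 at an unadjusted p under 0.05. With batch as a term it was 1 by the spike grouping and 2 by the low-signal grouping.

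**Figure D2:**
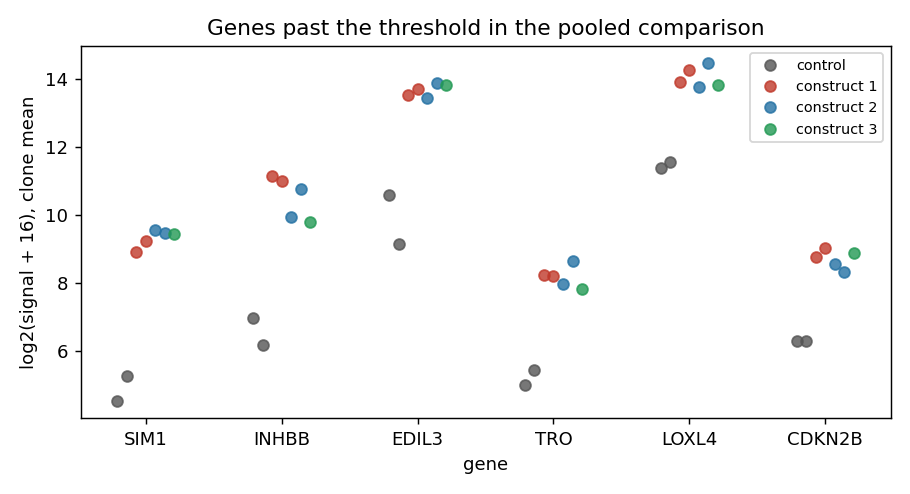
Clone means of log2(signal + 16) (vertical axis) for the 6 genes past the threshold in the pooled comparison (horizontal axis), each point a clone coloured by construct. For SIM1 the 5 clones labelled shKDM4C have signals between 469 and 747, against 7.21 and 23.5 in the controls.

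Cell cycle and mitosis genes were the list with the lowest values in clones labelled shKDM4C. All 63 tested members had a lower mean, and 60 of them lay below both controls in all 5 clones. The list mean was -4.07 and -3.30 in the clones of construct 1, -0.99 and -1.12 in those of construct 2 and -1.13 in construct 3, while the control clones lay at -0.03 and 0.03. CDC20, an activator of the anaphase-promoting complex, stood at -3.21, HMMR at -3.16, the cytokinesis scaffold ANLN at -2.93 and the mitotic kinase PBK at -2.86. Camera with a preset correlation called the list lower (adjusted p = 1.4e-25), and with an estimated correlation it did not pass (adjusted p = 0.536). No member passed in the pooled test, over all genes or adjusted over the list alone. In construct 1, 57 of the 63 members passed over all genes (limma) and 63 when adjusted over the list alone. In construct 2, 0 passed over all genes and 10 over the list alone. The adjusted p of the list by fry was 0.273 in the pooled comparison, 0.0271 in construct 1 and 0.2 in construct 2. DNA damage response and repair genes were called lower as well (mean -0.53, 22 of 25 members lower, camera adjusted p = 4.42e-05), with FANCI at -1.94, the histone variant H2AX at -1.76, BRCA1 at -1.53 and CHEK1 at -0.94. That call too was lost with an estimated correlation (adjusted p = 0.536 with an estimated correlation).

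Smaller downward calls fell on chromatin and ribosome genes. H3K9 methylation and heterochromatin genes had a mean of -0.36, with 18 of 29 lower (camera, adjusted p = 0.0406), a call lost in 12 of 27 alternatives (adjusted p = 0.536 with an estimated correlation). Its leading members were the lamin LMNB1 at -2.18, UHRF1 at -2.08 and the maintenance DNA methyltransferase DNMT1 at -1.31, genes that are also expressed with proliferation, and the histone methyltransferase SUV39H1 at -0.96. MYC-driven ribosome biogenesis genes had a mean of -0.40, with 21 of 24 lower (camera, adjusted p = 9.99e-05; adjusted p = 0.536 with an estimated correlation), among them LYAR at -0.90, the cap-binding factor EIF4E at -0.85, RRP9 at -0.82 and ODC1 at -0.79. Cytoplasmic ribosomal proteins went the other way, with 42 of 42 members higher and a mean of 0.46 (camera, adjusted p = 2.09e-12; adjusted p = 0.536 with an estimated correlation), including RPL31 at 0.74, RPL34 at 0.67, RPS19 at 0.61 and RPL12 at 0.59.

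Hypoxia targets were higher as a list, with 29 of 32 members higher and a mean of 1.06 (camera, adjusted p = 9.59e-10), a call lost when the correlation was estimated (adjusted p = 0.536 with an estimated correlation). DDIT4, an inhibitor of mTOR signalling, stood at 3.01, MXI1 at 2.72, STC2 at 2.44 and NDRG1 at 2.44, and 5 members were called when adjusted over the list alone. Glycolysis genes had 16 of 18 members higher (camera, adjusted p = 0.00016; adjusted p = 0.536 with an estimated correlation), led by ALDOC at 1.45, ENO2 at 0.91, GPI at 0.68 and HK2 at 0.68. Amino acid response genes driven by ATF4 had 29 of 31 higher and a mean of 0.88 (camera, adjusted p = 1.42e-07; adjusted p = 0.536 with an estimated correlation), where DDIT4 and STC2 led again, before NUPR1 at 2.20 and VLDLR at 1.72. P53 targets had 25 of 27 higher (camera, adjusted p = 4.37e-05, or 0.536 with an estimated correlation), with ACTA2 at 1.66, TP53INP1 at 1.47, GDF15 at 1.18 and SESN2 at 1.14. ACTA2 lay above both controls in 2 of 5 clones, and GDF15 stood at -1.28 in construct 3.

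Matrix glycoproteins and proteoglycans were higher in 33 of 40 members with a mean of 0.83 (camera, adjusted p = 0.000115), a call lost when the correlation was estimated (adjusted p = 0.536 with an estimated correlation). HAPLN1, which links hyaluronan to proteoglycans, stood at 5.26, the small proteoglycan ASPN at 3.27, the microfibril protein MFAP5 at 3.12 and the large proteoglycan VCAN at 2.52. MFAP5 had an SE of 2.13 (limma, unadjusted p = 0.179) and ran in opposite directions between the clones of constructs 1 and 2. When adjusted over the list alone, 2 members passed. Imprinted genes were higher in 15 of 17 members (mean 0.74, camera adjusted p = 0.00176, fry adjusted p = 0.0281, adjusted p = 0.536 with an estimated correlation), with MEST at 4.88, NDN at 1.67, SLC67A1 at 1.25 and SGCE at 1.10, and 4 were called when adjusted over the list alone. Cholesterol and fatty acid synthesis genes were higher in 22 of 28 members (mean 0.26, camera adjusted p = 0.0309, adjusted p = 0.536 with an estimated correlation), a call lost in 9 of 27 alternatives, where SCD stood at 1.34, FADS2 at 1.03, STARD4 at 0.76 and EBP at -0.75.

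Camera called 12 of 45 lists, 8 higher and 4 lower, and 11, 12 and 11 lists for constructs 1, 2 and 3. Of these 0 held with an estimated correlation (adjusted p = 0.536 with an estimated correlation for each of the pooled 12). The lists called were not the same in each construct. The H3K9 list passed in construct 1 (camera, adjusted p = 0.00337) but not in constructs 2 and 3 (0.121 and 0.0839). P53 targets (0.148) and MYC-driven ribosome biogenesis (0.29) did not pass in construct 3, nor cholesterol genes in construct 1 (0.706). All 12 pooled shifts kept their sign within the batches of both groupings, where batch A of the spike grouping holds 1 clone against 1. Of the other lists, interferon-stimulated genes had a mean of 0.04, NF-kB targets -0.19 and HOX genes 0.02, and none passed in camera (adjusted p from 0.628 to 0.988). Senescence-associated secretory factors had a mean of -0.32 and a median of 0.20 (camera, adjusted p = 0.988). Mean and median also had opposite signs for NF-kB targets, papillary dermal fibroblast genes, heat shock proteins and the BMP, Notch, Wnt and melanocyte lists, none of them called. Of the cyclin-dependent kinase inhibitors 5 of 7 were higher, with CDKN2B called when adjusted over the list alone (camera, adjusted p = 0.18; fry, adjusted p = 0.0132). Keratinocyte markers had a mean of 0.80 over 6 tested members, among which DSP stood at 3.81 (camera, adjusted p = 0.375). The 3'/5' ratio of ACTB, a measure of RNA integrity, was 1.57 ± 0.23 (SD, n = 5 clones) in clones labelled shKDM4C and 1.28 in the controls (two-sided exact permutation p = 0.19).

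**Figure D3:**
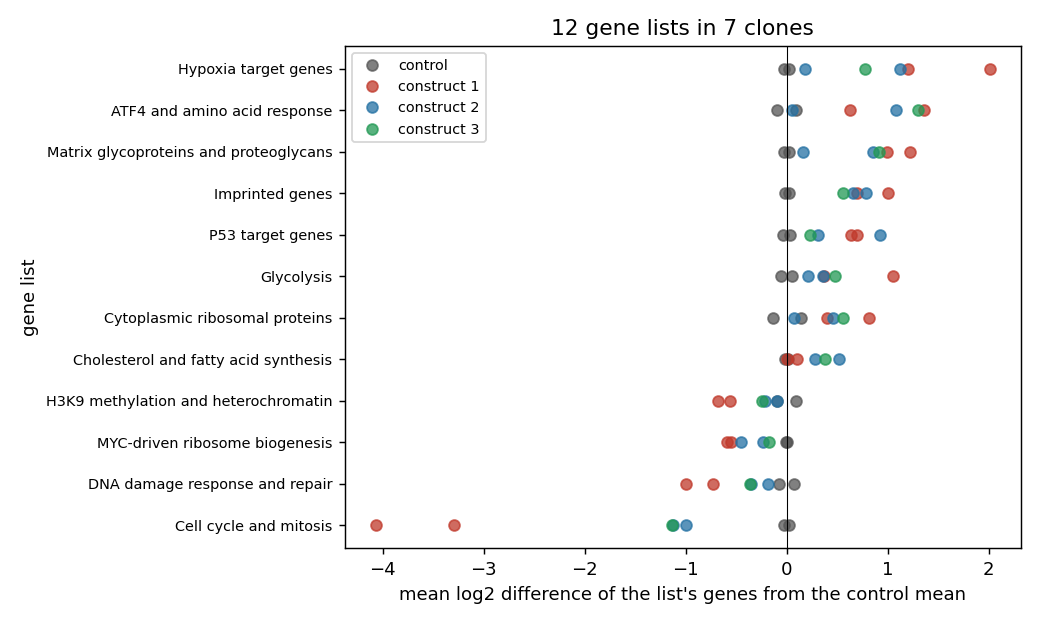
Mean log2 difference from the control mean (horizontal axis) of the genes of the 12 lists that camera called (vertical axis), each point a clone coloured by construct. For cell cycle and mitosis genes the clones of construct 1 stand at -4.07 and -3.30, and the others labelled shKDM4C between -1.13 and -0.99.

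Against the controls, construct 1 had 315 genes past the threshold, 68 higher and 247 lower. The split was nearer to even at an unadjusted p under 0.05 (999 higher and 1101 lower) and with the clone as a random block (635 higher and 721 lower without the replicate block, 584 and 686 with it). Mitotic genes led the falls: CDC20 by -5.75 ± 0.98 (SE; limma, adjusted p = 0.045), HMMR by -5.45, PBK by -5.10, NUF2 of the kinetochore by -5.05 and NEK2 by -4.99. For these but PBK, 1 of the 2 clones lay under the filter signal, so the sizes of those falls and their order are not fixed. The rises named were PAPPA, a protease of IGF-binding proteins, by 5.46 ± 0.69 (limma, adjusted p = 0.0166), and GASK1B by 5.36. LRRC32, RASGRP1 and ZNF423 had both controls under the filter signal and rose by at least 3.76, 3.48 and 3.18 with the controls set at it. Construct 2 had 0 genes past the threshold in limma and 730 at an unadjusted p under 0.05. With 1 clone, an effect of construct 3 cannot be told apart from a difference of that clone alone. Construct 3, a single clone whose error is taken from the other constructs, had 1, the membrane protein gene TMEM47, lower by -6.13 ± 0.37 (limma, adjusted p = 0.0316), and 692 at an unadjusted p under 0.05. Without control clone 1 or 2 the construct 1 count was 0 in limma, with 1160 or 1116 at an unadjusted p under 0.05; without its own clone 1 or 2 it was 161 or 156. Without either control clone or either clone of construct 1 the construct 3 count was 0 in limma, with 372 to 764 at an unadjusted p under 0.05, and without either clone of construct 2 it was 3.

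No gene passed the threshold in all 3 construct comparisons of the main fit. With the clone as a random block, 42 did without the replicate block (27 higher and 15 lower) and 31 with it (22 higher and 9 lower). In the main fit 241 genes had an unadjusted p under 0.05 (limma) with the same sign in all 3, 106 higher and 135 lower. Simulations without effects that shared the controls gave a mean of 51.2, and independent lists 1.67. Genes were drawn independently there and in the simulated correlations below. These simulations therefore do not show how widely such values vary when genes move together. An excess over them does not by itself establish a construct effect. GASK1B stood at 5.36, 4.65 and 3.91 in constructs 1, 2 and 3. With control clones under the filter signal set at it, HAPLN1 stood at no less than 3.82, 4.61 and 6.08 and SIM1 at no less than 2.80, 3.25 and 3.18. PAPPA, EDIL3, INHBB, SATB1, LDOC1, GDF5 and PPARG, the adipogenic nuclear receptor, were also among the 10 with the highest fitted means, though both controls of PPARG lay under the filter signal. Among the lower genes MALL stood at -3.11, -3.65 and -4.51 and ID1 at -3.82, -2.38 and -3.49; MMP10, IL13RA2, ANLN, TPD52, PBK and BUB1 were also among the 10 with the lowest means. Across genes, which are not independent replicates, log2 differences of constructs 1 and 2 correlated with r = 0.723, constructs 1 and 3 with 0.532 and constructs 2 and 3 with 0.56, against 0.503, 0.409 and 0.408 in simulations without effects that shared the controls. With a separate control clone for each construct, so that no control was shared, r was 0.431, 0.328 and 0.255. The covariance was then 0.258, 0.232 and 0.123, against 0.357, 0.331 and 0.221 with shared controls.

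Constructs 1 and 2 differed in 13 genes, all higher in construct 2 than in construct 1. Both directions occurred at an unadjusted p under 0.05 (577 of 928 higher in construct 2, the rest lower) and with the clone as a random block (236 higher and 82 lower without the replicate block, 210 and 58 with it). PAX8-AS1, a noncoding RNA gene, differed by 4.76 ± 0.26 (SE; limma, adjusted p = 0.0182), at -3.20 in construct 1 and 1.56 in construct 2. PBK differed by 3.76, ZNF367 by 3.41, RAD51AP1 by 3.35 and the kinetochore gene KNL1 by 3.08. All of the 13 but PAX8-AS1 lay below the controls in both constructs, less so in construct 2. PBK stood at -5.10 in construct 1 and -1.34 in construct 2, and KNL1 at -4.17 and -1.09. The count was 0 with batch as a term by the spike grouping and 27 by the low-signal grouping, 1 after quantile normalization, and 28 without construct 1 clone 2. It was 0 in limma without either control clone, construct 1 clone 1 or either clone of construct 2, with 627 to 1381 genes at an unadjusted p under 0.05.

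Clones that shared a construct differed widely, by a test that sets 1 clone against 1 and takes its error from the 2 arrays of a clone, which may be technical repeats. Control clones 1 and 2 differed in 3744 genes, 1843 higher and 1901 lower in clone 2. IGFBP2, a binding protein of insulin-like growth factors, had a signal of 14.8 in clone 1 and 7655 in clone 2 (limma over arrays, adjusted p = 9.61e-09), and PTGS2, the inducible cyclooxygenase, 41.4 and 8793 (adjusted p = 2.79e-12). GPAT2, ADIRF and PRXL2A were also higher in clone 2, and CCDC85A, PEAR1, PDE1C, FABP4 and F2RL2 lower. In 9 of the 10 the lower clone lay under the filter signal, so the sizes of those differences are not fixed. Without a single control array the count lay between 2307 and 3176, with the lowest when array 1 of control clone 2 was left out.

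The clones of construct 1 differed in 5742 genes and those of construct 2 in 6098. Clone 2 of construct 2 was deposited later than clone 1, so clone and deposit cannot be told apart in that comparison. The stromelysin MMP3 had signals of 34310 and 58.7 in clones 1 and 2 of construct 1 (limma over arrays, adjusted p = 6.34e-18), and the microfibril gene MFAP5 167 and 25690. ALDH1A1, PSG4, AMIGO2 and MKX were lower, and DCLK1, EPHA5, RGS4 and SCUBE3 higher, in clone 2 of that construct. MFAP5 ran the other way in construct 2, with 5936 in clone 1 and 90.4 in clone 2. The neuronal gene STMN2 had 16.9 and 24900 there (adjusted p = 7.72e-14), and LHX9, a LIM homeobox factor, 43.5 and 7839. CLEC2B, APCDD1 and PCDH10 were also higher in clone 2 of construct 2, and NFIB, ASB5, EFEMP1 and SLFN11 lower.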

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

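The tests of batch and of construct 1 alone were chosen after the cell cycle values were seen; the test of scaling was planned.

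Construct 2 lay above construct 1 in 13 genes by a test of the difference itself (limma), and 577 of 928 genes at an unadjusted p under 0.05 were higher in it. On the log2 scale the differences were 4.76 for PAX8-AS1, 3.76 for PBK, 3.41 for ZNF367, 3.35 for RAD51AP1, 3.08 for KNL1, 2.85 for CCNE2, 2.78 for RACGAP1, 2.70 for FAM83D, 2.54 for TMPO, 2.50 for FANCI, 2.46 for SGO2, 2.43 for KIF20B and 2.29 for GINS1. All of these genes but PAX8-AS1 lay below the controls in both constructs, less so in construct 2. Of lists, camera called cell cycle and mitosis genes higher in construct 2 (mean difference 2.62), as well as DNA damage response and repair (0.59), H3K9 methylation and heterochromatin (0.47) and cholesterol and fatty acid synthesis (0.34). It called hypoxia targets (-0.95), matrix glycoproteins and proteoglycans (-0.59), NF-kB targets (-0.53), glycolysis (-0.42), the ATF4 response (-0.42), TGF-beta targets (-0.37) and cytoplasmic ribosomal proteins (-0.34) lower in construct 2. None of the 11 calls held with an estimated correlation (adjusted p from 0.38 to 0.819).

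A single clone stood far from the other 4 labelled shKDM4C in 2 of 70 sets of values, where chance gives about 3.5. Endothelial and pericyte markers stood at -0.43 in construct 3 clone 1 against 0.04 to 0.22 in the others (gap over range 0.722). Numbered zinc finger genes stood at 0.27 in construct 1 clone 1 against 0.01 to 0.07 (gap over range 0.77).

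Cell cycle genes were lower in all 5 clones labelled shKDM4C, and several tables argue against technical accounts of that as the whole cause. Within batches, the shift closest to 0 was -0.97, from 1 clone against 1. After quantile normalization the list mean was -2.15, so scaling does not carry it. The shift closest to 0 outside construct 1 was -0.99, so construct 1 is not its sole source, although the shift was larger there. A slower proliferation of the selected clones, from the construct, from clonal selection or from culture density, stays open as a hypothesis that these arrays do not separate, and with KDM4C transcript higher in 4 of the clones no link to KDM4C loss was tested.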

How the results depend on the processing

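Batch terms, within-batch fits and the fit without construct 1 were chosen after the data were seen, and all gene counts are from limma. No direction reversed among the 24 named genes, the 12 called lists and KDM4C. For many alternatives this could not have come out otherwise. Named genes were chosen with every labelled clone mean on the same side of both controls. Leaving out clones, weighting them differently or fitting within batches therefore cannot reverse them. An estimated correlation or fry changes the test of a list and not its mean shift. Named genes kept their side of the threshold in 513 cases, lost it in 68 and gained it in 55; called lists kept it in 284 and lost it in 40, of which the H3K9 list lost it in 12 of 27, the cholesterol list in 9 and the others in 1 or 2. CDKN2B and INHBB lost their call in 15 alternatives, TRO in 14, LOXL4 in 11, EDIL3 in 9 and SIM1 in 4, within batches and without both clones of construct 1. The cause of the changes below was not tested, except where fewer clones or probe sets were fitted.

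The pooled count of 6 was 3 with a filter at the upper quartile, 2 with constructs weighted equally and 26 in the arrays deposited first (both control clones, construct 1 and construct 2 clone 1). With batch as a term it was 1 (spike grouping) and 2 (low-signal grouping), within spike batch B 1, within the low-signal batches 0 and 0, and without construct 1 it was 0 (589, 549 and 1012 at an unadjusted p under 0.05). Spike batch A holds 1 clone per arm and gave no test. Leaving out a clone gave 1 to 6. For construct 1, batch as a term gave 504 by the low-signal grouping, and leaving out a clone gave 0 to 393. The construct 3 count was 0 without a variance trend or with the low-signal batch, and 0 to 3 without a clone. Its fit could not be made without its clone or in the arrays deposited first. The 13 genes between constructs 1 and 2 became 1 after quantile normalization, 1 at an offset of 64, 6 without a filter, 27 with the upper quartile, 1 over all probe sets, 1 without a trend, 0 in the arrays deposited first, and 0 (spike) or 27 (low-signal) with batch. Leaving out a clone gave 0 to 28. Over all probe sets, 20 lists were called and 6961 probe sets differed between the control clones. With an estimated correlation 0 lists were called, and by fry 2. Leaving out a control array gave 2307 to 3176 genes between the control clones. The spread between arrays was 0.153 at an offset of 64. KDM4C stayed between 0.48 and 0.98 without each clone in turn and was 0.30 without both clones of construct 1. Genes near the filter signal of 61.7 are limited by background.

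Array 2 deviations correlated between clones at -0.08 to 0.09, so replicate numbers share only a number. Taking the clone as a random block without the replicate block gave 185 genes in the pooled comparison, 1356, 142 and 131 for constructs 1, 2 and 3, 318 between constructs 1 and 2, and 42 in all 3. With the replicate block these were 132, 1270, 107, 112, 268 and 31. Both fits used a single correlation for all genes and so treated the arrays of a clone as partly independent. Arrays treated as independent, which ignores the clones, gave 1448, 3559, 1013, 922, 1423 and 359.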

Other observations

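The tests of positional genes, of other cell types, of batch and of the spread between clone means, and the simulation of array noise, were chosen after the values were seen; the tests of other splits and of array 2 against array 1 were planned.

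Among the 45 lists tested, the median SD between clones of a construct was highest for senescence-associated secretory factors (1.28), NF-kB targets (1.12), reticular dermal fibroblast genes (1.001) and matrix glycoproteins and proteoglycans (0.875), against medians of 0.346, 0.362, 0.33 and 0.319 in random lists matched on signal. Mitochondrial respiratory chain genes varied little (0.186 against 0.288). Positional transcription factors and HOX genes had a median SD of 0.534 over 45 genes, above 99.9% of 10000 random lists. LHX9 had 5.86 and 12.94 (log2 scale) in the clones of construct 2, and PITX1 8.17 and 4.41 in the clones of construct 1. A hypothesis is that clones keep different positional codes, which may reflect the cells they were grown from; since the inflammatory lists vary more, the spread is not particular to positional genes.

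KDM4C signal was higher in 4 of the 5 clones labelled shKDM4C. The probe set lay at percentile 73.5 of signal, which argues against a reading at background. Within every batch of both groupings the signal was higher than in the control clone, by 0.491 to 0.779. The smallest of these differences came from 1 clone against 1 and so has no error of its own. The pooled difference of 0.66 has an SE of 0.492. With so few clones, neither a difference nor a share of batch in it is settled. A loss of KDM4C protein without a loss of transcript, a cleaved transcript still seen by the probe set, and a wrong label were not tested.

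Clones of 1 construct differed in 3744 to 6098 genes, with a median SD of 0.353 between clone means where noise that differs between the 2 arrays of a clone gives 0.12, which argues against such noise as the whole cause; noise shared by both arrays of a clone was not measured. The planned contrast of array 2 with array 1 called 0 genes (limma; 593 at an unadjusted p under 0.05) but decides nothing, since simulated array noise as large as the spread between clones gave 0 calls as well. For construct 1, of the genes that differed by 4-fold or more in both sets, 46.9% of 49 went the same way as in the controls and 21.3% of 108 as in construct 2. That argues against a shared batch of the low-signal grouping, which separates the clones of construct 1, as the whole cause of those large differences. In the spike grouping both clones of construct 1 lie in batch B, so there is no batch contrast to judge. The tree grouping, where construct 1 clone 2 stands alone, cannot be judged this way either. The clones of the control and of construct 2 lie in different batches in both groupings. Their differences correlated across genes with r = 0.456, against 0.275 for the controls and construct 1 and 0.061 for constructs 1 and 2. Between the controls and construct 2, 72.4% of 58 such genes went the same way (exact 95% interval 59.1% to 83.3%). The interval treats genes as independent and rests on 1 pair of clones each, so it measures no spread over clones or batches. Over all genes called in both, 2017 of 2502 went the same way in the controls and construct 1, 2525 of 2768 in the controls and construct 2, and 2447 of 3527 in constructs 1 and 2. Batch and clone therefore cannot be told apart, beyond what the low-signal grouping shows for the large differences of construct 1. Divergence between clones stays an untested biological hypothesis.

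Of the 21 splits of the 7 clones into 2 and 5, 2, the labels' own split included, gave at least 6 genes, so chance was not excluded. The highest other split, the clones of construct 1 against the rest, gave 178 genes, which points to a structure in which that construct stands apart. For lists, 5 splits with the labels' own gave at least 12, with 18 in the highest other split, so chance was not excluded there either.

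Cells of another type were tested in clones labelled shKDM4C with 6 lists of markers, of which 7 to 15 members each lay under the signal filter. At most 21.4% of a list's members exceeded both controls by 1 (log2) in a clone, which argues against a large share of such cells there beyond that in the controls. By signal averaged over clones, KRT14 lay at percentile 5.7, CDH5 at 7.8, ADIPOQ at 18.6, MLANA at 31.8, PTPRC at 37.8 and MYH11 at 44.5. PECAM1 lay at 66, DES at 63.3, TYR at 58.3 and FABP4 at 55.4, above the filter. The highest clone signal was 491 for DES, in a clone labelled shKDM4C, and 556 for FABP4, in control clone 1.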
